A study of Mus musculus with 6 samples.

How the data were processed

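HSF1 binding was measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in mouse striatal cell lines. STHdhQ7/Q7 cells carry wild-type huntingtin and STHdhQ111/Q111 cells carry knocked-in huntingtin with an expanded polyglutamine tract. They are called Q7 and Q111 cells here. Each line was sampled at its growth temperature of 33 °C and after 6 hours at 42 °C. Per the labels' protocols, chromatin was crosslinked with formaldehyde, precipitated with an HSF-1 antibody, gel-selected, amplified by PCR and sequenced on an Illumina Genome Analyzer II. The 6 samples comprise 4 HSF1 libraries, each with 1 peak list, and 2 control IgG libraries, which were not analysed here. Each group holds 1 library, so no comparison between groups has a replicate check.

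Each deposited list gives the chromosome, start, end, name and score of every peak. The peak names carry the MACS prefix, and MACS version 1.4.0rc2 and the mouse build mm9 are named in the submitters' processing notes. The lists have no header, and the score was taken to be -10 times the base-10 logarithm of the peak's p-value, as in the usual output of MACS 1.4. This reading is an inference. The scores deposited by the authors start between 90.0 and 90.5 in all 4 lists. At 42 °C, 73 peaks of the Q7 list and 12 of the Q111 list are tied at 3100. A further 12 peaks of the Q7 list score above 3100, up to 3217, and none of the Q111 list does. The highest-scoring peaks named below for Q7 at 42 °C therefore lie above the tie, whereas those named for Q111 are the tied peaks. The aligner, the background library, read filters and total read numbers are not given in the sources used here. The sequencing depth behind the lists is therefore unknown. The number of peaks called depends on depth and on enrichment, and no interval below covers either. Because the score also depends on them, scores were used to rank or filter peaks within a list and never compared between lists. The authors' files hold 1 list per library, so peaks were taken as called per library. Peaks of 1 list never overlapped each other. Coordinates are on mm9 and counted from 1.

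Lists were compared by interval overlap, with a minimum of 1 shared base, in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9). The overlap of the lists at 42 °C was checked against bedtools 2.31.1, which gave the same count. Shares of peaks carry 95% Wilson intervals, which cover counting error only. Overlap beyond chance was tested by placing the peaks of a list at random on their own chromosomes 1000 times, between the outermost peaks of all 4 lists. This baseline ignores mappability and open chromatin and is therefore low. Scores of shared and unshared peaks of 1 list were compared by the difference of medians, with a two-sided permutation test over peaks (100000 resamples) and Benjamini-Hochberg adjustment over the 4 lists. Peaks are not replicates, and such p-values describe these libraries, not the conditions. Peaks of all 4 lists that overlapped were also merged into regions, and each region was classified by the libraries that held a peak in it.

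On simulated data, all 648 overlaps planted in a list of the size of the Q7 list at 42 °C were recovered. The planted peaks were slightly shifted copies of Q111 peaks, so this checks the code only. The random placement test called 0 of 40 random lists of 292 peaks. These lists were drawn by the placement rule of the test, so the result does not bear on mappability or open chromatin. The checks of both tests used fewer placements and resamples than the comparisons themselves. The permutation test called 23 of 400 random splits of 500 peaks at the 0.05 level, and 397 of 400 splits with a planted 1.5-fold shift.

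The comparisons, the alternatives and the rule for the peaks named were fixed before the data were examined. The rule names the 10 peaks with the highest score of each list and of the shared, Q7-only and Q111-only sets at 42 °C, with ties kept and shared peaks ordered by the Q7 score. Alternatives were a minimum score of 100, autosomes only, an overlap of at least 50% of the shorter peak, a distance of up to 500 bases, the longer list trimmed to as many top peaks as the shorter, and removal of peaks with 3 or more others of their list within 20 kb. Tests of peak position relative to genes, of heat shock elements in the peak sequence and of gene lists near peaks had also been planned. They need an mm9 annotation or genome, and the gene table at hand is on another build. Coordinates were not moved between builds, so these tests were not run and peaks are identified by position, without gene names.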

Results

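HSF1, the transcription factor that drives the heat shock response, was mapped in 4 ChIP-seq libraries from mouse striatal cell lines with wild-type (Q7) or polyglutamine-expanded (Q111) huntingtin. The design asked where HSF1 bound in each line at 33 °C and after 6 hours at 42 °C. Each combination of cell line and temperature was represented by 1 library, so the values below have no replicate error. The authors' lists held 260 peaks for Q7 and 292 for Q111 cells at 33 °C, and 6173 peaks for Q7 and 2161 for Q111 cells at 42 °C. Together the peaks covered 0.121 Mb and 0.174 Mb at 33 °C, and 3.28 Mb and 1.01 Mb at 42 °C, for Q7 and Q111 respectively. Median peak widths at 33 °C were 420.5 bases in Q7 cells (95% interval over peaks 402 to 445) and 549 bases in Q111 cells (524 to 569). At 42 °C they were 495 bases in Q7 cells (491 to 500) and 444 bases in Q111 cells (435 to 451). Peaks lay on the autosomes and the X chromosome in every list. Read depth was unknown for all libraries.

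Merging overlapping peaks gave 6577 regions. Of these, 6224 held a peak only at 42 °C, 43 only at 33 °C, and 163 in all 4 libraries. The most frequent class, 4380 regions, held a peak in Q7 cells at 42 °C and in no other library. A further 1477 regions held a peak at 42 °C in both cell lines and none at 33 °C, and 367 held one at 42 °C in Q111 cells alone.

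**Figure D1:**
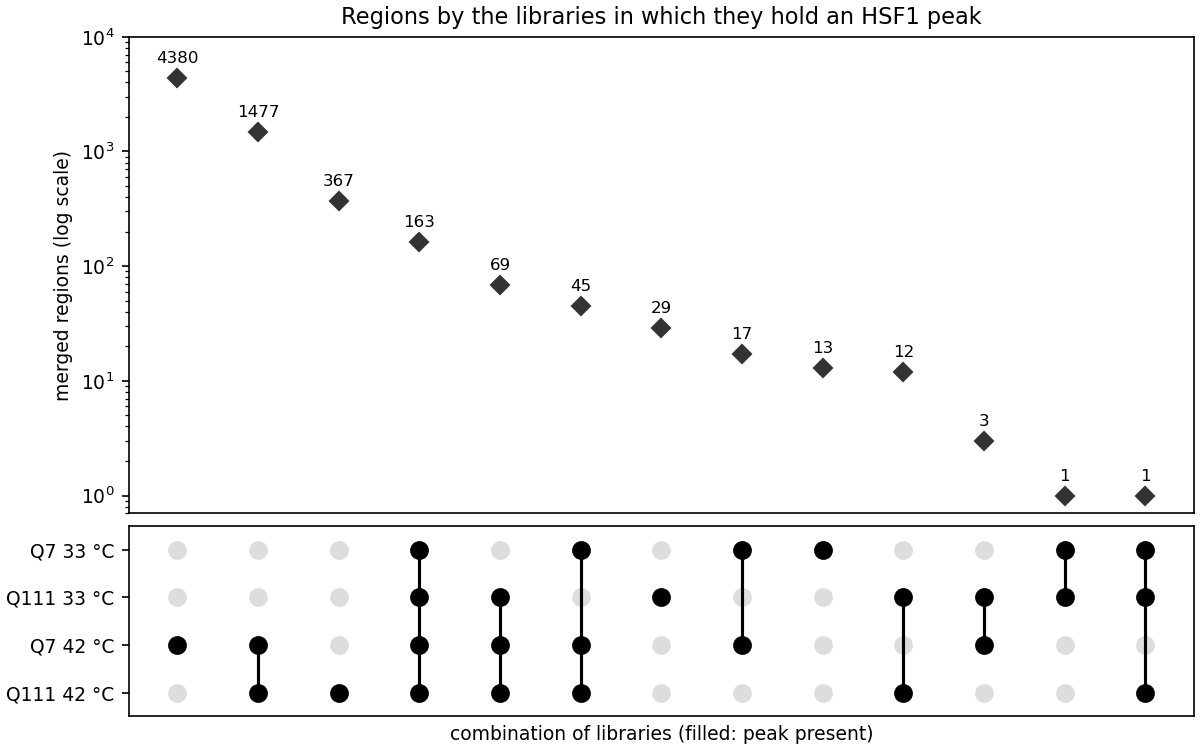
Number of merged regions (log scale, upper panel) for each combination of libraries that held an HSF1 peak (filled circles, lower panel). Regions with a peak at 42 °C in Q7 cells alone (4380) outnumber those with a peak at 42 °C in both cell lines and none at 33 °C (1477) and those with a peak at 42 °C in Q111 cells alone (367).

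The first comparison asked how heat shock changed HSF1 occupancy in wild-type cells. In Q7 cells the 42 °C list held 23.7 times as many peaks as the 33 °C list, and covered 27.2 times as many bases. Of the 260 peaks at 33 °C, 245 or 94.2% (95% interval 90.7 to 96.5) overlapped a 42 °C peak. Conversely, 5935 of the 6173 peaks at 42 °C had no counterpart at 33 °C, and 238, or 3.86% (3.40 to 4.37), did. With the 42 °C list trimmed to its 260 highest-scoring peaks, 29.2% of the 33 °C peaks overlapped one of them and 27.3% of these overlapped a 33 °C peak. Random placement gave a mean of 0.727 and at most 5 overlapping peaks for the 33 °C list, and the p of 0.001 is the smallest that 1000 permutations of position can give.

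The highest-scoring peak of Q7 cells at 33 °C lay on chromosome 15 from 81229928 to 81230706, with a score of 845. It was followed by peaks on chromosome 1 (55144548 to 55145236, score 733), chromosome 5 (31190150 to 31191287, score 678) and chromosome 11 (48647198 to 48648310, score 658). The others among the 10 highest lay on chromosome 11 from 58115542, on chromosome 10 from 90644016, 79711571 and 12642183, on chromosome 7 from 86610956 and on chromosome 18 from 36961358. All 10 overlapped a peak in each of the other 3 libraries. The 10 highest-scoring peaks of Q7 cells at 42 °C had no Q7 counterpart at 33 °C in 7 cases. They were led by peaks on chromosome 13 from 49438892 to 49439642, chromosome 18 from 61050671 to 61051643, chromosome 10 from 58797645 to 58798360 and chromosome 16 from 18416045 to 18416764. The remaining ones started on chromosome 5 at 125871827 and 22915414, on chromosome 10 at 93082973, on chromosome 12 at 111933990, on chromosome 4 at 56016368 and on chromosome 16 at 43574093. Of these 10 peaks, 3 overlapped a peak of Q7 cells at 33 °C, on chromosome 18 and at 43574093 on chromosome 16 and 22915414 on chromosome 5. All 10 overlapped a peak of Q111 cells at 42 °C. These 10 peaks scored above the 73 Q7 peaks tied at 3100. If the tie marks a cap of the score, these 10 need not be the strongest Q7 sites. The 100 highest-scoring peaks take in the tied ones, and 44 of the 100 overlapped a Q7 peak at 33 °C. The 15 peaks at 33 °C with no Q7 counterpart at 42 °C were low in their list, with scores of at most 146, the highest lying on chromosome 3 from 87709923 to 87710288.

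The second comparison asked the same of cells with expanded huntingtin. In Q111 cells the 42 °C list held 7.40 times as many peaks as the 33 °C list, and covered 5.78 times as many bases. Of the 292 peaks at 33 °C, 259 or 88.7% (84.6 to 91.8) overlapped a 42 °C peak. At 42 °C, 1899 of 2161 peaks had no counterpart at 33 °C, and 262, or 12.1% (10.8 to 13.6), did. With the 42 °C list trimmed to its 292 highest-scoring peaks, these shares were 42.1% of the 33 °C and 39.7% of the 42 °C peaks. At most 3 peaks of the 33 °C list overlapped after random placement (permutation of position, p = 0.001, the smallest possible). Whether the heat shock response of the 2 lines differed in size could not be tested with 1 library each.

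The 2 highest-scoring peaks of Q111 cells at 33 °C lay close together on chromosome 11, from 68853632 to 68854977 (score 1508) and from 68875478 to 68876879 (score 1429). The next were on chromosome 11 from 58115543 to 58116396 (score 1258), on chromosome 1 from 55144505 to 55145213 (score 1230) and on chromosome 5 from 125873280 to 125873938 (score 1159). The other 5 started on chromosome 10 at 12642160, chromosome 3 at 96303919, chromosome 9 at 40608752, chromosome 15 at 81229802 and chromosome 18 at 36961354. All 10 overlapped a peak in each of the other 3 libraries, and 5 of the 10 highest Q7 peaks at 33 °C lay at one of these sites. At 42 °C, 12 Q111 peaks were tied at the top score of 3100. Of these, 9 overlapped a peak in every other library. They lay on chromosome 1 from 55144568, chromosome 10 from 121340938, chromosome 15 from 81229883, chromosome 17 from 45709256, chromosome 4 from 40669047, chromosome 5 from 125873078 and 150438005, chromosome 8 from 75799644 and chromosome 9 from 40608825. The peaks on chromosome 15 from 50003739 and on chromosome 2 from 174683817 lacked a Q7 peak at 33 °C, and the peak on chromosome 15 from 75772880 lacked a Q111 peak at 33 °C. The widest of the 12, on chromosome 17, extended to 45711185 and measured 1930 bases.

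The third comparison asked how HSF1 binding under heat shock differed between the cell lines. The Q7 list held 2.86 times as many peaks as the Q111 list at 42 °C, and most Q111 sites lay within it. Of the Q111 peaks, 1781 of 2161 or 82.4% (80.8 to 84.0) overlapped a Q7 peak, whereas 1773 of 6173 Q7 peaks, or 28.7% (27.6 to 29.9), overlapped a Q111 peak. This left 4400 peaks in Q7 cells and 380 in Q111 cells without a counterpart. Random placement of the Q7 peaks gave at most 15 overlaps (permutation of position, p = 0.001, the smallest possible). With the Q7 list trimmed to its 2161 highest-scoring peaks, 63.5% of them overlapped a Q111 peak and 64.0% of the Q111 peaks overlapped one of them. Centres of shared peaks lay a median of 46 bases apart, and 16.9% of the Q7 peaks were narrower than their Q111 counterpart.

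Peaks found in both lines scored higher within their list than peaks found in 1 line. In Q7 cells the median score at 42 °C was 571 for shared and 143 for unshared peaks, and in Q111 cells it was 248 for shared and 120 for unshared peaks. For both lists, the permutation test over peaks gave an adjusted p of 1e-05, the smallest it can give. Peaks near the lowest score are the most easily missed in another library. Such a difference can therefore arise without any change of binding, and the test does not bear on the lines. In the lowest decile of the Q7 list by score, 21 of 617 peaks or 3.40% (2.24 to 5.15) overlapped a Q111 peak. In the decile with scores from 316 to 493 this share was 46.8% (42.9 to 50.8), and in the highest decile it was 90.9% (88.4 to 93.0), with 56 of 618 peaks unshared. The share of Q111 peaks overlapped by a Q7 peak was 56.0% (49.4 to 62.5) in the lowest decile and 99.5% (97.4 to 99.9) in the highest, in which 1 of 217 peaks was unshared.

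**Figure D2:**
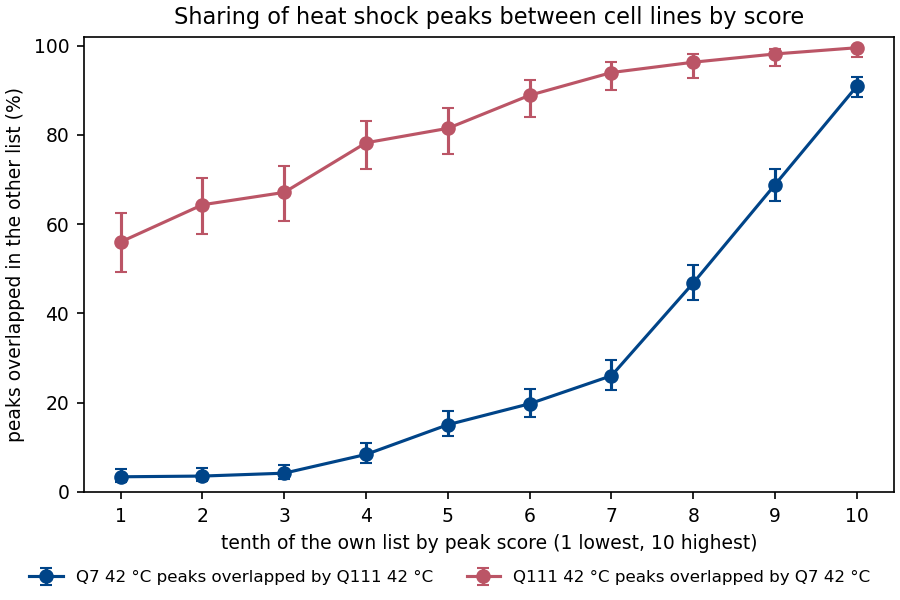
Percentage of 42 °C peaks that overlap a 42 °C peak of the other cell line (vertical axis), by decile of the own list ordered by peak score (horizontal axis), with 95% Wilson intervals as bars. Sharing of Q7 peaks rises from 3.40% to 90.9%, and sharing of Q111 peaks from 56.0% to 99.5%.

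The highest-scoring Q7 peaks without a Q111 counterpart at 42 °C lay on chromosome 8 from 91539358 to 91540058 (score 2581), chromosome 6 from 93216641 to 93217266 (score 2181) and chromosome 18 from 81429532 to 81430308 (score 1921). They were followed by peaks on chromosome 14 from 37613008, chromosome 11 from 33871880, chromosome 16 from 20426063, chromosome 15 from 62152503, chromosome 8 from 11382034, chromosome 2 from 128597266 and chromosome 1 from 88369024, the last with a score of 1463. None of these 10 regions held a peak at 33 °C in either line. The highest-scoring Q111 peak without a Q7 counterpart lay on chromosome 13 from 38190590 to 38191177, with a score of 1297. The next ones scored 644 on chromosome 8 from 93761101 to 93761561 and 611 on chromosome 10 from 94724617 to 94724948. The others started on chromosome 17 at 68324092 and 69464708, chromosome 3 at 30403336, chromosome 6 at 17169438, chromosome 12 at 96585993, chromosome 10 at 116460476 and chromosome 2 at 27627588, where the score was 453. None of these 10 held a peak at 33 °C.

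The fourth comparison asked whether the lines differed without heat shock. The lists were of similar length, with 1.12 times as many peaks in Q111 as in Q7 cells. A Q111 peak overlapped 184 of the 260 Q7 peaks, or 70.8% (65.0 to 76.0), and a Q7 peak overlapped 177 of the 292 Q111 peaks, or 60.6% (54.9 to 66.0). At most 1 Q7 peak overlapped a Q111 peak after random placement (permutation of position, p = 0.001, the smallest possible). Shared peaks again had higher scores within their list, with the same limit as at 42 °C. Medians were 190 against 113 in Q7 cells and 294 against 125 in Q111 cells (permutation test over peaks, adjusted p = 1e-05 for both). Where a Q7 and a Q111 peak overlapped, the Q111 peak was wider in 84.2% of 184 pairs, by a median of 144.5 bases. The order was the reverse at 42 °C, where the Q111 peak was wider in 16.9% of pairs. Depth was unknown, so a width difference between libraries cannot be told apart from one between lines.

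Of the 353 regions with a peak at 33 °C, 165 had one in both lines and 188 in 1 line. Among these 188, 114 held a peak of both lines at 42 °C, namely 69 with a Q111 and 45 with a Q7 peak at 33 °C. Sites occupied at 33 °C stood high in the 42 °C lists. In the Q7 list, peaks without any counterpart at 33 °C had a median score of 173 (95% interval over peaks 169 to 178). Within the Q7 list at 42 °C, the 62 peaks with a 33 °C peak in Q7 but not in Q111 cells had a median score of 1648 (95% interval over peaks 1022 to 2482). The 176 peaks with a 33 °C peak in both lines had a median of 619 (531 to 709), and the 74 peaks with one in Q111 but not in Q7 cells had a median of 591 (421 to 918). The first group exceeded the second (permutation test over peaks, adjusted p = 0.00012) and the third (permutation test, adjusted p = 0.00016; 4 comparisons in this family, chosen after the data were examined). Within the Q111 list at 42 °C the corresponding medians were 654, 683 and 576, and the first group was not separated from the second (permutation test, adjusted p = 0.836) or the third (adjusted p = 0.779). These medians cover only sites with a Q111 peak at 42 °C. Of the 62 peaks of the first group in the Q7 list, 45 overlapped a Q111 peak at 42 °C. The same held for all 176 of the second and 71 of the 74 of the third group.

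Of the 100 highest-scoring Q7 peaks at 42 °C, 44 overlapped a Q7 peak at 33 °C (95% interval 34.7% to 53.8%) and 31 a Q111 peak at 33 °C (22.8% to 40.6%). Among these 100 peaks, 21 had a 33 °C peak in Q7 cells alone and 8 in Q111 cells alone (exact binomial test, two-sided, adjusted p = 0.0482 over 4 rank groups). Below rank 1000 the balance was the reverse, with 19 in Q7 cells alone and 38 in Q111 cells alone (exact binomial test, adjusted p = 0.0482). The test takes peaks as independent, although some are neighbours, and the rank groups were chosen after the data were examined. Ranking by the Q7 score may itself favour sites called in Q7 cells. Of the 100 highest-scoring Q111 peaks at 42 °C, 59 overlapped a Q111 and 49 a Q7 peak at 33 °C. The test was not run on that list, so it does not show that the excess is particular to Q7 cells. The chromosome 13 window described below held 17 regions that lacked only a Q7 peak at 33 °C and 1 that lacked only a Q111 peak. How many of the 38 lay there was not counted.

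**Figure D3:**
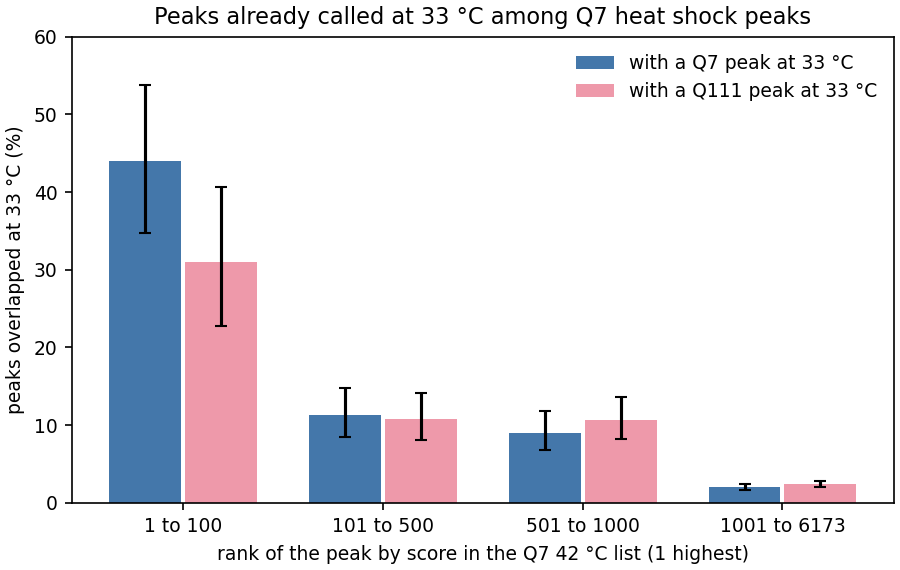
Percentage of Q7 peaks at 42 °C that overlap a peak at 33 °C in Q7 or in Q111 cells (vertical axis, starting at 0), by rank of the peak in the Q7 list at 42 °C (horizontal axis), with 95% Wilson intervals as bars. Among the 100 highest-ranked peaks, 44 overlap a Q7 and 31 a Q111 peak at 33 °C.

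Some of the peaks at 33 °C were clustered. The window of chromosome 13 from 21 to 24 Mb, chosen after the densest 1 Mb windows had been counted, held 35 of 260 Q7 peaks, or 13.5% (9.84 to 18.1), and 51 of 292 Q111 peaks, or 17.5% (13.5 to 22.2). At 42 °C it held 78 Q7 peaks, or 1.26% of that list (1.01 to 1.57), and 77 Q111 peaks, or 3.56% (2.86 to 4.43). The 2 lines thus had almost equal numbers of peaks in this window at 42 °C, although the Q7 list was longer. All 35 Q7 and all 51 Q111 peaks of the window at 33 °C overlapped a peak of each line at 42 °C. Of the window's 79 merged regions, 28 held a peak in all 4 libraries and 17 in all except Q7 at 33 °C. From 33 to 42 °C the number of peaks in the window rose, from 35 to 78 in Q7 and from 51 to 77 in Q111 cells, while its share fell because the lists grew more elsewhere.

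**Figure D4:**
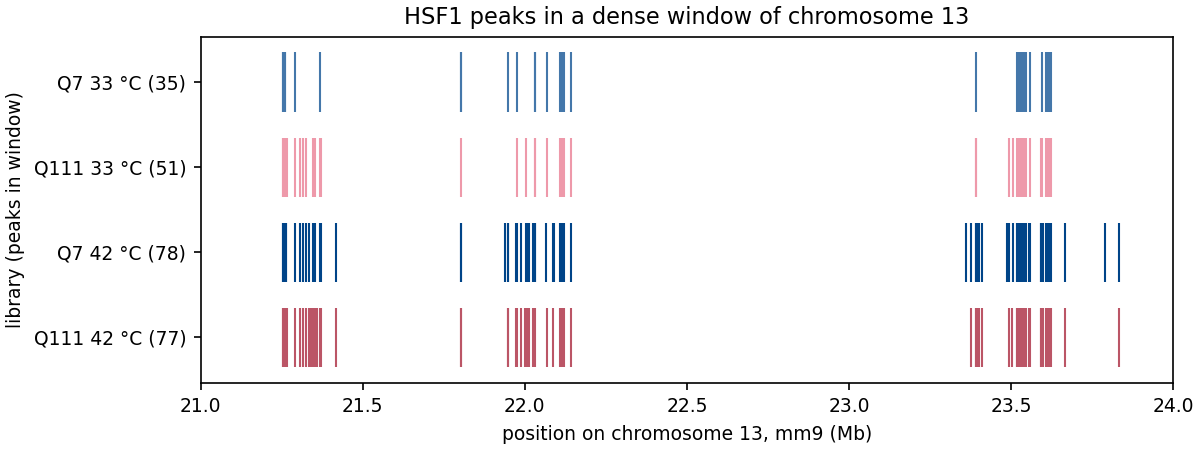
Centres of HSF1 peaks (vertical ticks) between 21 and 24 Mb of chromosome 13 (mm9, horizontal axis) in the 4 libraries, 1 row each, with the number of peaks in parentheses. The peaks fall into the same groups in all 4 rows, and the rows hold 35, 51, 78 and 77 peaks.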

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

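Of 76 planned repeats of the peak numbers, ratios, overlaps and score differences under other settings, 62 stayed within the interval of the reported value or, for numbers and tests, on the same side, and none changed direction. Peak numbers and their ratios moved by less than 1.5 times under a minimum score of 100 and on autosomes alone. Both settings left most peaks in place. Trimming the longer list moved 6 of its 8 overlaps beyond their intervals, and removing dense clusters moved 7 of 8. Score differences between shared and unshared peaks remained past the 0.05 level in all 4 lists under the 3 alternatives tried (permutation tests of 2000 resamples). Requiring an overlap of 50% of the shorter peak, or allowing 500 bases between peaks, moved no overlap beyond its interval. Allowing 500 bases ended none of the 20 named differences between the lines at 42 °C. The 50% rule could not end any, since these peaks share no base with the other list. A minimum score of 100 moved 1 overlap, that of Q111 with Q7 peaks at 42 °C, from 82.4% to 84.2%. The higher Q7 score at 42 °C of sites occupied at 33 °C in Q7 but not Q111 cells, compared with sites occupied in both, was a difference of 1029 and ranged from 887 to 1329 under 3 alternatives chosen after seeing the data. In the Q111 list at 42 °C the same difference was -28.6 and ranged from -29.6 to 156, changing direction with a minimum score of 100 (156, permutation test over peaks, p = 0.28) and past the 0.05 level under none of the 3. Removal of dense clusters was not tried on these differences. The chromosome 13 window from 21 to 24 Mb held 28 regions with a peak in all 4 libraries. A further 17 lacked only a Q7 peak at 33 °C, and 1 lacked only a Q111 peak at 33 °C. The median score of the window's Q7 peaks at 42 °C was 407. The cause of the differences was not tested.

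The longer list was also trimmed to its top peaks. At 42 °C, 63.5% of Q7 and 64.0% of Q111 peaks were then shared. Between temperatures, 29.2% of Q7 peaks at 33 °C and 27.3% of those at 42 °C were shared in Q7 cells, and 42.1% and 39.7% in Q111 cells. Lists of 42 °C peaks trimmed to 260 and 292 peaks leave out most of their sites, which lowers the overlap of 33 °C peaks by construction. Without dense clusters, removed from each list separately, the overlap of 33 °C with 42 °C peaks was 83.9% in Q7 and 77.2% in Q111 cells, and the reverse 3.01% and 8.90%. At 42 °C, 27.2% of Q7 and 78.6% of Q111 peaks were shared, and at 33 °C 60.8% of Q7 peaks. Part of this fall comes from construction, since a site can be dense in 1 list and not in the other. No paired analysis was possible because each group has 1 library. Other settings for gene positions, heat shock elements and gene lists were not run, because no mm9 genome or annotation was used. Depth was unknown, so a peak missing from a list is not evidence that HSF1 was absent from the site.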

Other observations

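The comparisons of peaks by 33 °C class, by rank and by window, and all tests in this part, were chosen after the data had been seen. Few sites were occupied at both temperatures in 1 cell line and absent from both lists of the other. For Q7 there were 17 such regions, the highest-scoring on chromosome 8 from 125572026 to 125572705 (score 1335 at 42 °C) and chromosome 15 from 64454074 to 64454823 (score 619). For Q111 there were 12, the highest-scoring on chromosome 14 from 76273294 to 76273900 (score 366) and chromosome 5 from 23370666 to 23371053 (score 299). At 33 °C the strongest Q111 peak without a Q7 counterpart lay on chromosome 14 from 51708935 to 51709576 (score 819) and was a peak of both lines at 42 °C. The strongest Q7 peak at 33 °C without a Q111 counterpart, on chromosome 7 from 29652460 to 29652823 (score 398), was also a peak of both lines at 42 °C.

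Apart from chromosome 13, the windows of 1 Mb richest in peaks at 33 °C lay on chromosome 11 from 68 to 69 Mb, with 10 Q7 and 8 Q111 peaks, and on chromosome 6 from 128 to 129 Mb, with 9 in each. At 42 °C the window of chromosome 13 from 23 to 24 Mb was still the richest, with 37 Q7 and 35 Q111 peaks. Outside chromosome 13, in Q7 cells at 42 °C, chromosome 10 from 80 to 81 Mb held 32 peaks, chromosome 19 from 5 to 6 Mb held 26 and chromosome 2 from 167 to 168 Mb held 22. In Q111 cells, chromosome 2 from 27 to 28 Mb held 12 peaks and chromosome 10 from 80 to 81 Mb held 11. The X chromosome held 1 of 260, 2 of 292, 82 of 6173 and 31 of 2161 peaks in the Q7 and Q111 lists at 33 °C and the Q7 and Q111 lists at 42 °C.

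The Q111 list at 42 °C was shorter than the Q7 list, and the peaks it lacked were mostly weak ones. Sharing rose by 87.5 percentage points from the lowest to the highest decile of the Q7 list, which is what a less sensitive Q111 library (fewer reads or weaker enrichment) would give for part of the difference, and a graded loss of binding could give it too. A uniform loss of sensitivity as the whole cause was tested in the top 20% of the Q7 list by score. There, 150 of 153 peaks with a Q7 peak at 33 °C were shared (98.0%), against a mean of 84.2% and at most 93.5% in 10000 draws of score-matched peaks without one, a gap of 13.8 points. Over the whole Q7 list, 221 of 238 were shared (92.9%), against a mean of 64.6% and at most 73.1% in the draws, a gap of 28.2 points. Of these 238 peaks, 176 also had a Q111 peak at 33 °C, and all 176 were shared. Of the 62 without one, 45 were shared. Most of the peaks compared were thus already called in Q111 cells, which the draws did not match. The gap in the top 20% was not split this way. Such gaps also arise without a change of binding, because a second Q7 call selects peaks whose true signal exceeds their score. Simulated libraries with a uniform loss gave gaps averaging 7.26 and reaching 12.4 points in the top 20% (48 libraries), and averaging 11.8 and reaching 17.5 points over the whole list (50 libraries). Both observed gaps exceed the simulated ones, but the simulation rests on assumed settings, so this cause stays open. Reduced HSF1 binding in Q111 cells and a less sensitive library cannot be told apart without read totals and replicates.

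The 33 °C peaks found in Q7 but not in Q111 cells included many of the strongest Q7 heat shock sites, and 44% of the top 100 Q7 peaks at 42 °C had a Q7 peak at 33 °C, against 11.3% among the next 400. This fall with rank was not particular to the Q7 library at 33 °C: 31% of the same top 100 and 10.8% of the next 400 had a Q111 peak at 33 °C. In the Q111 list at 42 °C, 59% of the top 100 and 27% of the next 400 had a Q111 peak at 33 °C. There, 49% and 24.5% had a Q7 peak at 33 °C, so Q111 led in its own list. Peaks with a 33 °C peak in 1 line alone numbered 21 for Q7 and 8 for Q111 in the top 100 of the Q7 list, and 17 and 15 in the next 400. A generally less sensitive Q111 library at 33 °C would give few sites called in Q111 alone. Yet 74 Q7 peaks at 42 °C had a 33 °C peak in Q111 but not in Q7 cells, compared with 62 of the opposite kind. The Q111 list was also the longer one (292 against 260 peaks), which such a library would not by itself give. With 1 library per line and unknown depth, these counts do not exclude it. The chromosome 13 window held 17 regions of the first kind and 1 of the second with peaks of both lines at 42 °C. Nor do the counts bear on the top 100, where Q7 led. A small share of heat-shocked Q7 material or reads in the Q7 library at 33 °C would produce the excess of Q7 in the top 100, but the fall with rank seen for both lines does not decide it, and it remains open. Partial HSF1 activity in unheated Q7 cells may produce the excess as well and was not tested. The excess may also come from ranking by the Q7 score, since Q111 led in the top 100 of its own list. In the Q111 list at 42 °C, the 46 sites occupied at 33 °C in Q7 but not Q111 cells had a median score of 654. It was 683 for sites occupied at 33 °C in both lines, and the groups were not separated (permutation test, adjusted p = 0.836). These medians leave out Q7 sites without a Q111 peak at 42 °C. In the Q7 list, 45 of the 62 peaks of the first kind overlapped such a peak, against all 176 of the second.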
